A study of Homo sapiens with 58 samples.

How the data were processed

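RNA-seq was run on 58 libraries of total RNA from H1 cells, a wild-type human embryonic stem cell line. The libraries were made with LM-seq from lysates of cultures in multiwell plates, per the labels. Of these, 12 form a daily series with 3 libraries on each of 4 days (Day0 to Day3), and 46 form a time course of presomitic mesoderm with 2 libraries at each of 23 time points, every 30 min from 30 to 690 min. Groups, times and replicate numbers were taken from the labels. The labels give the media of the daily steps but neither the medium nor the zero point of the time course, and they do not say that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

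The expected counts per gene, which need not be whole numbers, were deposited for 19084 genes without mitochondrial genes, and the program that made them is not given in the sources used here. The TPM values in the second table were rescaled by the authors so that the listed genes have the same sum in each library, as the deposited values show. Reads were aligned with Bowtie 0.12.2, and the builds hg19 and mm8 are both listed, per the submitters' processing notes. The annotation and the use made of the mouse build are not given in the sources used here. The human annotation at hand belongs to another build, so genes are named by the symbols in the deposited tables and no coordinates are printed. No column of either table was left without a sample.

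Total expected counts ran from 3.16 to 7.81 M in the daily libraries (median 5.13 M) and from 2.53 to 8.96 M in the time course (median 4.12 M). A count of 0 allows up to 3 counts, which is 0.384 to 0.949 CPM per daily library and 0.335 to 1.18 CPM per course library. A fold against a group whose libraries were all at 0 is given as a lower bound from 3 counts over the whole group. With 1 to 3 counts in the lower group, the ratio of pooled counts is given with its exact 95% counting interval. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Replicate libraries correlated at r 0.887 to 0.971 in the daily series and 0.920 to 0.983 in the course, across genes on log2 CPM. A chi-square per degree of freedom of at least 7.78 and 3.74 showed no pair close enough to be a duplicate.

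Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood F tests, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. For the days, 12765 genes passed the filter. A test with 3 degrees of freedom asked for any change over the 4 days, and a gene was called between successive days at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. A gene was day-specific if it was called higher on that day than on each of the other three. For the course, 13653 genes passed the filter. A test with 22 degrees of freedom asked for any difference among the 23 time points. A linear term tested for a trend, called with a fitted change of at least 1 log2 unit over the course. A cosine and a sine term of period 300 min beside a quadratic trend tested for a rhythm. Levels are CPM, given as the mean ± SD with n libraries.

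The period of HES7 was found by least squares on log2 CPM (prior count 2) over 180 to 480 min in steps of 1 min, with a 95% profile interval. The peak times of rhythm-called genes were fitted separately in the first 11 and the last 12 time points. The course was set beside the days by the Pearson correlation, across the 1000 genes with the smallest p in the daily test, of log2 CPM centred on the gene means.

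The test set included 24 gene lists: markers of pluripotency, mesendoderm, presomitic mesoderm, somite, definitive endoderm, neural tissue, lateral and cardiac mesoderm, intermediate mesoderm, endothelium and blood, sclerotome and myotome, and trophoblast; the Notch pathway; targets of Wnt, FGF-ERK and BMP-TGFβ; genes of retinoic acid, immediate early response, G1/S, G2/M, the circadian clock, glycolysis, cholesterol synthesis and stress; and all HOX genes. They were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. For each list the number of called members is given over all genes tested and adjusted over the list alone. The lists share some genes. Rhythm calls in each list were compared with other genes by a one-sided Fisher's exact test.

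Named genes follow a rule fixed before the data were examined, as were the tests, the lists and the first set of other settings. Per transition it takes the 6 largest rises and 6 largest falls at 20 CPM or more in the higher day with the same direction in all 9 library pairs, up to 3 called members with the smallest adjusted p from each list called by camera, and 17 stage markers. For the course it takes HES7, the 10 rhythm genes of largest fold at 5 CPM or more, rhythm-called members of the Notch, Wnt and FGF lists, and the 6 largest trend rises and falls at 5 CPM or more. It takes 4 genes per day among the day-specific genes. Further list members are named as examples.

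Other settings chosen beforehand were a replicate block, DESeq2 size factors, the DESeq2 1.42.0 test, no filter on low counts, limma on log2(TPM + 1) or log2(TPM + 0.1) for genes with a mean TPM of at least 1, other fold limits, only the 2 days compared, other trends and periods, the course without its first 3 time points, random time orders, and leaving out each library or each replicate series. Chosen after the data were seen were a copy index as a covariate, a step between 270 and 300 min, separate fits before and after that step, the list test on the trend, and keeping the genes tested with all libraries when a library was left out. The copy index is the mean centred log2 ratio, per library, of 8 processed gene copies (retrotransposed, intron-less copies of other genes) to their parent genes. The ratio was taken on unscaled counts with 1 added, and each pair was centred on its mean over all libraries. The index is thus a deviation from the average library and not the level of copies against parents. The added count raises it in libraries of low depth where copies are scarce. A further 14 such pairs were kept as a check, of which 10 were used after pairs with low copy levels were left out. Correlations across libraries were tested with 1e+05 permutations, which give 1e-05 as the smallest possible p. They shuffle single libraries and ignore the order and pairing of time points.

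The code was tested on simulated counts with planted changes in 200 genes at an average of 5 CPM or more. Genes were simulated independently, without a signal shared across libraries such as the copy index. The recovery therefore does not cover genes of lower level or data with such a signal. For Day1 against Day0, 71% of genes with 3-fold changes were recovered among 12629 tested, with 8 other genes called. For the rhythm test, 55% were recovered at 1.5-fold peak to trough among 13440 genes, 82% at 2-fold and 99% at 4-fold. For the trend, 99% were recovered at 4-fold.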

Results

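Gene expression was measured by RNA-seq in H1 human embryonic stem cells that were led towards somites, the segments of the embryo that later form vertebrae and muscle. The daily series had 12 libraries, 3 from each of 4 days. Day0 was undifferentiated cells and Day1 was mesendoderm, the common precursor of mesoderm and endoderm, in 100 ng/mL activin A with 3 µM of the Wnt activator CHIR99021. Day2 was presomitic mesoderm, in 3 µM CHIR99021, 100 ng/mL FGF2, 100 ng/mL of the BMP antagonist NOGGIN and 2 µM of the activin and nodal receptor inhibitor A83-01. Day3 was somite cells, in 1 µM of the MEK inhibitor PD0325901, 2.5 µM of the Wnt inhibitor IWR1, 2 µM A83-01 and 100 ng/mL NOGGIN. The time course had 46 libraries of presomitic mesoderm, 2 at each of 23 time points from 30 to 690 min. The title of the series concerns synchronized oscillation of HES7, a repressor of the segmentation clock. Total expected counts per library were 5.66 to 7.65 M at Day0, 4.36 to 5.95 M at Day1, 3.16 to 3.6 M at Day2, 4.52 to 7.81 M at Day3 and 2.53 to 8.96 M in the time course. Levels are CPM as mean ± SD, with n = 3 libraries per day and n = 2 per time point, and adjusted p-values are from edgeR unless another tool is named.

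Day1 against Day0 asked what changed as stem cells became mesendoderm. Many mesendoderm genes rose. T (brachyury) rose from 0.511 ± 0.453 to 193 ± 40.1 CPM (334-fold, adjusted p = 5.15e-09). The transcription factors MIXL1 and EOMES reached 91.3 ± 15.3 CPM (247-fold, adjusted p = 2.48e-06) and 356 ± 47.2 CPM (165-fold, adjusted p = 1.65e-06). Secreted inhibitors of Wnt and nodal rose with them. CER1 reached 442 ± 98.6 CPM (590-fold, log2 SE 0.43, adjusted p = 2.06e-09), and DKK1 reached 441 ± 27.1 CPM (1340-fold, log2 SE 0.75, adjusted p = 2.01e-07). DKK4, another Wnt inhibitor, reached 148 ± 21.5 CPM (ratio 1460, counting interval 404 to 12100) from 2 counts at Day0. The endoderm and heart regulator GATA6 reached 135 ± 12.5 CPM (ratio 1310, interval 361 to 10800), also from 2 counts. FGF17, a growth factor, was at least 286-fold higher (43.6 ± 2.31 CPM), and the caudal homeobox gene CDX1 at least 213-fold higher (32.8 ± 5.68 CPM), both from 0 counts at Day0. The core pluripotency factors were still present, although SOX2 was called lower (log2 -1.307, adjusted p = 0.024). POU5F1 was 1052 ± 272 CPM at Day0 and 665 ± 64.8 CPM at Day1 (adjusted p = 0.0778), and NANOG was 96.3 and 68.9 ± 11.5 CPM (adjusted p = 0.606).

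Other genes of the stem cell state did fall in Day1. The telomere-binding TERF1 fell 7.64-fold from 621 ± 44.5 to 81.3 ± 13 CPM (adjusted p = 2.42e-08). The DNA methyltransferase DNMT3B fell 3.61-fold from 1621 ± 264 CPM (adjusted p = 3.5e-07) and the deubiquitinase USP44 from 265 to 30.7 CPM (adjusted p = 4.01e-05). The largest falls also took in the palmitoyltransferase ZDHHC22 (from 77.6 ± 27.3 to 2.0 CPM, adjusted p = 1.88e-05), the junction gene CGNL1 (from 186 ± 31.7 to 11.8 CPM, adjusted p = 9.22e-07) and CTTNBP2 (from 33.7 to 2.04 CPM, adjusted p = 3.77e-05). Of 16 pluripotency genes 9 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 1.54e-15). Of 17 mesendoderm genes 12 rose (15 adjusted over the list alone; adjusted p = 4.53e-58). Of 15 Wnt targets 9 rose, also 9 adjusted over the list alone (adjusted p = 6.25e-20). Among them SP5 rose to 88.7 ± 4.8 CPM (ratio 578, interval 198 to 2800) and the feedback inhibitor NKD1 from 3.98 to 74.3 ± 11.3 CPM (adjusted p = 1.06e-05). Of 15 presomitic genes 8 rose (9 adjusted over the list alone; adjusted p = 1.21e-15), among them the Wnt agonist RSPO3 by 9.03-fold. Of 15 somite genes 5 rose, also 5 adjusted over the list alone (adjusted p = 3.24e-05). These included FST, an activin antagonist, by 8.06-fold to 231 ± 32.8 CPM (adjusted p = 4.31e-06), EPHA4 by 3.73-fold (adjusted p = 1.44e-05) and CDH11 by 5.14-fold (adjusted p = 1.6e-05). Of 6 definitive endoderm genes CER1 and GATA4 rose and SHISA2 fell, as they did adjusted over the list alone (adjusted p = 1.46e-05). With an estimated correlation the camera adjusted p was 0.000719 for pluripotency genes, 0.000127 for mesendoderm genes and 0.00306 for Wnt targets. It was 0.00403 for presomitic, 0.0286 for somite and 0.0116 for definitive endoderm genes.

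At Day1 3 further lists were called higher with camera but not with an estimated correlation. Stress genes had 5 of 15 members higher (6 adjusted over the list alone; adjusted p = 3.65e-06, and adjusted p = 0.0618 with an estimated correlation). Those that rose include the amino acid synthesis genes PSAT1 (2.05-fold, adjusted p = 0.00218) and ASNS (2.31-fold, adjusted p = 0.00163) and the kinase-like TRIB3 (7.85-fold, adjusted p = 0.0037). Cholesterol synthesis had 1 of 16 higher, as adjusted over the list alone (camera adjusted p = 0.000201, and adjusted p = 0.317 with an estimated correlation). Lateral and cardiac mesoderm had 3 of 7 higher (5 adjusted over the list alone; adjusted p = 0.0103, and adjusted p = 0.216 with an estimated correlation). Its 3 genes were GATA4, BMP4 and MYL7. The apelin receptor gene APLNR, in the mesendoderm list, rose from 0.85 to 91.8 ± 14.7 CPM (adjusted p = 5.98e-09). No call was made for the remaining lists. Their genes higher and lower are given with the camera adjusted p, and with counts adjusted over the list alone in brackets where these differ. At Day1 they were Notch 0 and 0 of 12 (0.612), FGF-ERK targets 0 and 3 [0 and 4] of 16 (0.272), BMP-TGFβ targets 2 and 1 [7 and 1] of 13 (0.0598), retinoic acid 2 and 0 of 11 (0.103) and immediate early 2 and 1 [5 and 2] of 14 (0.127). For cell functions they were G1/S 0 and 0 of 18 (0.713), G2/M 0 and 1 of 18 (0.0598), circadian clock 1 and 0 of 12 (0.903), and glycolysis 1 and 0 of 18 (0.657). For other tissues they were neural 0 and 1 of 11 (0.397), intermediate mesoderm 0 of 5 (0.193), endothelium and blood 0 of 3 (0.844), sclerotome and myotome 0 of 4 (0.747), trophoblast 0 of 4 (0.984) and HOX 0 of 12 (0.242). With the copy index as a covariate the FGF-ERK targets were called lower (adjusted p = 0.00186). DUSP6, a phosphatase gene that ERK induces, fell 5.55-fold to 52 CPM at Day1.

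Between Day0 and Day1 661 of 12765 genes were called, 347 higher and 314 lower. The count was 437 without Day1 replicate 1 and 1139 when only the 6 libraries of both days were fitted. Those higher were 226 without Day0 replicate 2. Those lower were 199 and 193 without Day1 replicate 1 and Day1 replicate 2, and 183 with the copy index, whose mean was -0.188 at Day0 and 0.847 at Day1. The index ran from -0.386 to -0.0167 at Day0, 0.402 to 1.11 at Day1, 1.68 to 2.08 at Day2 and -1.08 to 1.31 at Day3. These ranges do not overlap between successive days, so as a covariate the index takes up part of the day difference. Daily calls lost with it need not be due to the copies. Several named calls also depend on single libraries. PAX3, a dermomyotome gene, rose from 3.40 to 9.32 CPM (adjusted p = 0.0214; 0.0863, 0.104 and 0.0989 without Day0 replicates 1 and 2 and Day1 replicate 3, 0.0945 and 0.0814 with log2(TPM + 1) and log2(TPM + 0.1) in limma). SOX2, a pluripotency and neural factor, fell by 1.31 log2 (adjusted p = 0.024; 0.0625, 0.0721, 0.0687 and 0.122 without Day0 replicates 2 and 3 and Day1 replicates 1 and 2). SHISA2, an inhibitor of FGF and Wnt receptors, fell 9.80-fold (adjusted p = 0.0183; 0.0863, 0.0638, 0.0678 and 0.0876 without the same libraries in turn, 0.0612 with log2(TPM + 0.1)). BMP4 rose 4.82-fold (adjusted p = 0.0264; 0.0953, 0.108 and 0.0503 without Day0 replicates 1, 2 and 3, 0.0551 and 0.114 without Day1 replicates 2 and 3, 0.0631 with the index, 0.0583 and 0.0612 with log2(TPM + 1) and log2(TPM + 0.1)). MYL7, a heart myosin gene, was at least 17.8-fold higher at 2.67 CPM (adjusted p = 0.0193; 0.0586, 0.0653 and 0.06 without Day0 replicates 1, 2 and 3, 0.0512 without Day1 replicate 2, 0.0631 with the index). GATA4 rose (ratio 257, interval 46.1 to 10200; adjusted p = 0.0111; 0.0592 and 0.0562 without Day0 replicates 2 and 3, 0.0549 with the index). IDO1, a tryptophan-degrading enzyme, fell from 20.2 to 1.16 CPM (adjusted p = 0.0126; 0.0538 and 0.142 without Day0 replicates 2 and 3, 0.0667 and 0.0672 without Day1 replicates 2 and 3, 0.0851 with the index). The falls of TRIML2 (from 41.9 to 1.14 CPM, adjusted p = 3.94e-04) and the retinol esterase LRAT (from 135 ± 125 to 7.09 CPM, adjusted p = 0.0015) had an adjusted p of 0.0885 and 0.174 with the index, and that of LRAT 0.0841 with log2(TPM + 0.1). With the index the errors of these lost calls widened. Without and with it the log2 change was -5.195 (SE 0.732) and -5.482 (1.658) for TRIML2, -4.221 (SE 0.728) and -3.375 (1.272) for LRAT and -4.12 (SE 0.921) and -3.992 (1.196) for IDO1. It was 7.458 (SE 1.687) and 6.476 (1.803) for GATA4, 6.83 (SE 1.638) and 6.364 (1.774) for MYL7 and 2.27 (SE 0.594) and 2.391 (0.685) for BMP4. The log2 rise of PSAT1 was 0.878 and 0.914 without Day0 replicate 1 and Day1 replicate 2 and 0.922 and 0.923 with log2(TPM + 1) and log2(TPM + 0.1), and that of ASNS 0.951 with the index, under the limit of 1. TBX6, a regulator of presomitic mesoderm, was at least 11.9-fold higher, at 1.80 CPM (adjusted p = 0.00818). MSGN1, DLL1, TCF15, MEOX1 and FOXC2 did not pass (adjusted p = 0.411, 0.476, 0.744, 0.596 and 0.415), nor did DLL3 and LFNG (0.368 and 0.149), which were called without Day0 replicate 3 (0.0112) and without Day0 replicate 1 (0.0428).

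**Figure D1:**
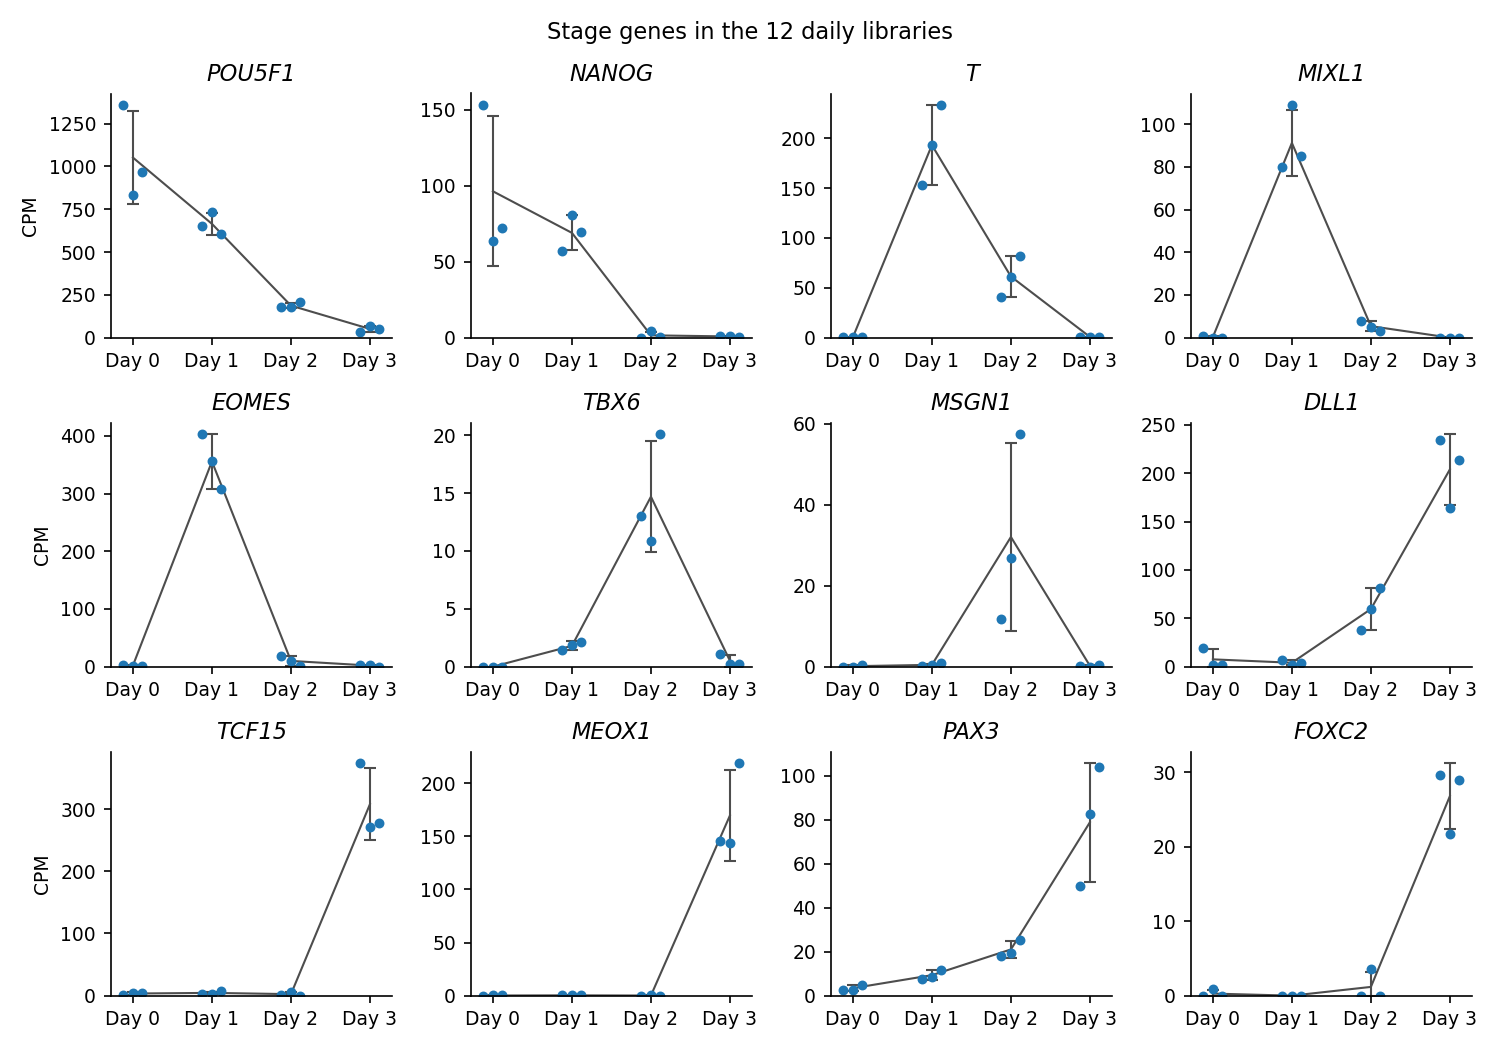
CPM of 12 stage markers on Day0 to Day3; points are libraries, lines join the means and bars are ± SD (n = 3). T, MIXL1 and EOMES were highest at Day1, MSGN1 was highest at Day2, and TCF15, MEOX1, PAX3 and FOXC2 were highest at Day3.

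Day2 against Day1 asked what changed as mesendoderm became presomitic mesoderm. Several presomitic and Notch genes rose. MSGN1, a master regulator of presomitic mesoderm, rose from 0.45 to 32.0 ± 23.2 CPM (67.0-fold, log2 SE 0.92, adjusted p = 3.83e-04). The Notch ligands rose, DLL1 to 59.6 ± 21.9 CPM (15.2-fold, adjusted p = 0.0015) and DLL3 to 59.4 ± 11.7 CPM (9.09-fold, adjusted p = 0.00159). The Notch modifier LFNG went from 9.72 to 71.9 ± 15.2 CPM (7.39-fold, adjusted p = 1.76e-05) and RSPO3 to 243 ± 105 CPM (8.33-fold, adjusted p = 1.92e-05). ALDH1A2, the enzyme that makes retinoic acid, went from 2 counts to 96.3 ± 64 CPM (ratio 759, interval 210 to 6270; adjusted p = 9.45e-07). Many mesendoderm genes fell in the same step. CER1 dropped to 0.624 CPM (adjusted p = 6.08e-09), NODAL from 369 ± 28.7 to 2.11 CPM (178-fold, adjusted p = 3.73e-05) and EOMES to 9.96 CPM (adjusted p = 2.77e-05). GATA6 fell to 5.86 CPM (adjusted p = 1.37e-05) and DKK4 to 0 counts (at least 463-fold lower). T fell to 61.3 ± 20.8 CPM (adjusted p = 0.00115). POU5F1 fell 3.55-fold to 187 ± 16.6 CPM (log2 SE 0.23, adjusted p = 6.77e-05). NANOG fell to 1.54 CPM (adjusted p = 5.64e-05) and the nodal co-receptor TDGF1 from 538 ± 68.1 to 12.0 CPM (adjusted p = 1.08e-06).

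HOX genes, which set position along the trunk, came on at Day2: 8 of 12 rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 5.39e-08). HOXB3 was at least 86.9-fold higher, at 16.9 CPM, and HOXB4 rose to 15.5 CPM (ratio 243, interval 43.6 to 9580). Of 17 mesendoderm genes 11 fell (13 adjusted over the list alone; adjusted p = 5.06e-15). Of 16 pluripotency genes 8 fell, among them DPPA4 from 303 to 70.8 CPM, and 1, SOX2, rose (the same counts adjusted over the list alone; adjusted p = 3.26e-07). Of 12 Notch genes 3 rose (4 adjusted over the list alone; adjusted p = 0.000821). With an estimated correlation the camera adjusted p was 0.00403 for HOX, 0.0116 for mesendoderm, 0.00403 for pluripotency and 0.0268 for Notch genes. The remaining calls were lost with an estimated correlation. Presomitic genes were higher in 8 and lower in 2 of 15 (9 and 3 adjusted over the list alone; camera adjusted p = 0.000996, and adjusted p = 0.0905 with an estimated correlation). Somite genes were higher in 5 of 15 (7 adjusted over the list alone; adjusted p = 0.000201, and adjusted p = 0.051 with an estimated correlation). Among them CDH11, a cadherin gene, rose 3.36-fold to 324 ± 90 CPM. Retinoic acid genes were higher in 4 and lower in 1 of 11 (5 and 1 adjusted over the list alone; adjusted p = 0.00491, and adjusted p = 0.0788 with an estimated correlation). The binding protein gene CRABP2 rose 2.23-fold to 252 CPM (adjusted p = 8.02e-04; log2 0.958 with log2(TPM + 1) and 0.961 with log2(TPM + 0.1), under the limit). CYP26A1, which degrades retinoic acid, fell from 134 to 6.93 CPM (adjusted p = 4.93e-06). BMP-TGFβ targets were lower in 4 of 13 (5 adjusted over the list alone; adjusted p = 0.00214, and adjusted p = 0.072 with an estimated correlation). ID1, a direct BMP target, fell from 16.3 to 0.647 CPM, and the feedback genes SMAD7 and SKIL fell from 35.6 to 1.11 CPM and from 123 to 23.4 CPM.

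Lists tied to growth and to other cell types moved at Day2 as follows. Stress genes fell in 5 of 15, also 5 adjusted over the list alone (adjusted p = 0.00936, and adjusted p = 0.258 with an estimated correlation), among them PSAT1 by 3.37-fold, TRIB3 by 12.2-fold and ASNS by 2.45-fold. Cholesterol synthesis fell in 2 of 16, also 2 adjusted over the list alone (adjusted p = 0.00844, and adjusted p = 0.509 with an estimated correlation), with MVD 2.75-fold lower. Definitive endoderm had 1 of 6 higher and 2 lower (1 and 3 adjusted over the list alone; adjusted p = 0.0145, adjusted p = 0.0922 with an estimated correlation and adjusted p = 0.175 with the copy index). The chemokine receptor gene CXCR4 rose 5.30-fold, and FOXA3, a gut endoderm factor, was at least 16.2-fold lower. Sclerotome and myotome genes rose in 2 of 4 (4 adjusted over the list alone; adjusted p = 0.00763, and adjusted p = 0.0643 with an estimated correlation). They were the cartilage regulator SOX9 by 4.41-fold (adjusted p = 0.00136) and the muscle filament gene DES. There was no call at Day2 for Wnt targets with 2 higher and 3 lower [2 and 4] of 15 (0.242), FGF-ERK targets 1 and 1 of 16 (0.893) and immediate early 1 and 3 [2 and 4] of 14 (0.657). Nor was there for G1/S 0 and 0 of 18 (0.402), G2/M 0 and 0 of 18 (0.272), circadian clock 1 and 0 [0 and 0] of 12 (0.786), or glycolysis 0 and 2 of 18 (0.697). The tissue lists without a call were neural 1 and 1 of 11 (0.242), lateral and cardiac mesoderm 0 and 1 of 7 (0.24, but called lower with the copy index, 0.0386), intermediate mesoderm 1 and 0 of 5 (0.52), endothelium and blood 1 and 1 of 3 (0.95) and trophoblast 0 of 4 (0.935). For the circadian list the median and mean differed in sign, and for endothelium and blood the median and test were negative and the mean positive. The mean copy index was 1.92 at Day2, the highest of the 4 days. Some neural transcripts were highest there too, with STMN2, a neuronal gene, at 443 CPM against 193 at Day1, MAP2 at 205 against 83.3 and PAX6 at 54.9 against 23 CPM. Others were not: SOX2 was highest at Day0, ZIC2 fell from 163 to 39.9 CPM at Day2, and NES was highest at Day3.

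In all, 1499 genes changed from Day1 to Day2, 457 higher and 1042 lower. With TPM values in limma the split was 287 higher and 1616 lower with pseudocount 1, and 267 and 1616 with 0.1. With no minimum fold it was 1107 higher and 1462 lower. The total was 698 with the copy index (212 higher and 486 lower) and 875 without Day1 replicate 2 (227 and 648). Index ranges did not overlap between Day1 and Day2, so the lower count with the index need not be due to the copies. Further large rises were those of the lipid transporter ABCG1 (57.4 ± 18.6 CPM, ratio 299, interval 102 to 1450) and TMEM132C (114 ± 13.7 CPM, adjusted p = 9.45e-07). They also held the sodium-calcium exchanger SLC8A3 (72.0 ± 48.2 CPM, adjusted p = 7.74e-05) and the Wnt ligand WNT8A (37.1 ± 31 CPM, adjusted p = 0.00281). Further large falls were those of the junction gene CLDN7 (41.2 to 0 CPM, at least 129-fold lower), the calcitonin receptor CALCR (69.1 CPM to 1 count, ratio 643, interval 115 to 25400) and RGS16 (49.0 CPM to 1 count, ratio 459, interval 82.3 to 18100). TBX6 rose from 1.80 to 14.7 ± 4.81 CPM (adjusted p = 0.0217), with an adjusted p of 0.0649, 0.0796, 0.0562 and 0.0654 without Day1 replicates 1, 2 and 3 and Day2 replicate 3, and 0.167 with the index. SOX2 rose by 1.15 log2 (adjusted p = 0.0247; 0.122, 0.0533 and 0.0772 without Day1 replicate 2 and Day2 replicates 1 and 2, 0.222 with the index, 0.0543 and 0.0623 with log2(TPM + 1) and log2(TPM + 0.1)). PAX3 rose by 1.17 log2 (adjusted p = 0.0247; 0.0787, 0.0935 and 0.0569 without Day1 replicates 1 and 2 and Day2 replicate 3, 0.0552 and 0.0633 with log2(TPM + 1) and log2(TPM + 0.1), 0.0533 with only the libraries of both days). DES rose 6.35-fold from 2.28 CPM (adjusted p = 0.0446; 0.055 without Day0 replicate 3, 0.118 and 0.137 without Day1 replicates 1 and 3, 0.05 and 0.168 without Day2 replicates 2 and 3, 0.0555 and 0.0515 without Day3 replicates 2 and 3, 0.0697 with the index, 0.0637 with only the libraries of both days). FOXA3 had an adjusted p of 0.0141, and 0.0525 without Day1 replicate 2; MVD had 0.0093, and 0.0684 without that library and 0.0898 with the index. MIXL1 fell from 91.3 to 5.40 CPM (adjusted p = 1.68e-04; 0.0643 with the index). For calls lost with the index, the log2 change without and with it was 3.011 (SE 0.839) and 2.593 (1.086) for TBX6, 2.666 (SE 0.894) and 3.39 (1.102) for DES and -4.077 (SE 0.519) and -3.626 (1.128) for MIXL1, with wider errors. It was 1.153 (SE 0.338) and 0.693 (0.333) for SOX2 and -1.46 (SE 0.354) and -1.197 (0.416) for MVD. TCF15, MEOX1 and FOXC2 did not pass (adjusted p = 0.342, 0.435 and 0.0767). However, TCF15 was called lower without Day2 replicate 2 (0.036) and FOXC2 higher without Day2 replicate 1 (0.0449) or 3 (0.0389) and with no filter on low counts (0.0364). HES7 was under the count filter in the daily series, at 0 CPM at Day1, 1.04 ± 0.938 CPM at Day2 and 0.558 CPM at Day3. MESP2, a segment border factor, was under it too, at 0.12 CPM at Day3.

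Day3 against Day2 asked what changed as presomitic mesoderm became somite cells. Several somite genes came on. TCF15 (paraxis), needed for epithelial somites, rose from 2.43 to 308 ± 57.5 CPM (133-fold, log2 SE 0.59, adjusted p = 9.76e-07), and the homeobox gene MEOX1 from 1 count to 170 ± 43 CPM (ratio 1660, interval 298 to 65700). RIPPLY1, which ends TBX6 activity at the segment border, went from 0 counts to 69.8 ± 42.8 CPM (at least 236-fold higher). PAX3 rose from 21.0 to 78.9 ± 27 CPM (3.75-fold, adjusted p = 0.001). Several early mesoderm genes fell. T fell from 61.3 to 0.765 CPM (log2 -6.40, SE 0.43, adjusted p = 1.21e-07) and MSGN1 117-fold to 0.216 CPM (adjusted p = 1.75e-04). RSPO3 fell 21.6-fold to 11.3 CPM (adjusted p = 6.15e-07) and the Wnt ligand WNT5B from 140 ± 53.7 to 1.64 CPM (adjusted p = 1.59e-05). In the medium with MEK and Wnt inhibitors, several feedback targets of FGF-ERK fell. SPRY4 dropped by 265-fold from 75.5 ± 22.1 to 0.226 CPM (log2 SE 0.47, adjusted p = 3.97e-08) and IL17RD by 27.7-fold from 220 ± 77.7 CPM (adjusted p = 1.44e-07). ETV4, an ERK-induced transcription factor, fell from 28.4 to 0.737 CPM (adjusted p = 7.86e-06) and DUSP6 by 19.9-fold to 7.03 CPM.

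By list, 9 of 15 somite genes rose and 1, EPHA4, fell at Day3 (10 and 1 adjusted over the list alone; camera adjusted p = 3.76e-09). PDGFRA, a growth factor receptor gene, rose 5.23-fold to 261 CPM. Of 15 presomitic genes 8 fell and 1, DLL1, rose (10 and 1 adjusted over the list alone; adjusted p = 1.87e-09). Of 16 FGF-ERK targets 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 3.63e-16). The gene that rose was CIC, a repressor that ERK signalling relieves. With an estimated correlation the camera adjusted p was 0.00963 for somite genes, 0.00963 for presomitic genes and 0.00403 for FGF-ERK targets. Lost with an estimated correlation were 6 calls. Wnt targets fell in 8 and rose in 1 of 15 (9 and 1 adjusted over the list alone; adjusted p = 2.56e-05, and adjusted p = 0.0653 with an estimated correlation). SP5 fell from 60.0 ± 18.6 to 0.624 CPM (adjusted p = 7.1e-06) and NKD1 by 6.35-fold (adjusted p = 3.68e-04). The growth regulator MYC was the gene that rose, 6.46-fold to 26.8 CPM (adjusted p = 3.25e-04). Mesendoderm genes fell in 6 and rose in 2 of 17, as adjusted over the list alone (adjusted p = 0.000114, and adjusted p = 0.0864 with an estimated correlation). MIXL1 was at least 33.8-fold lower, while GATA6 rose 2.47-fold and APLNR 3.24-fold to 556 ± 217 CPM. Pluripotency genes fell in 3 and rose in 1 of 16 (4 and 1 adjusted over the list alone; adjusted p = 0.00714, and adjusted p = 0.0532 with an estimated correlation). POU5F1 fell to 50.9 ± 18.8 CPM (log2 -1.88, adjusted p = 5.86e-05) and L1TD1 fell 8.28-fold. The gene that rose was PODXL, a surface sialomucin, by 4.31-fold. Glycolysis fell in 3 and rose in 1 of 18, as adjusted over the list alone (adjusted p = 0.0148, and adjusted p = 0.066 with an estimated correlation). The glucose transporters SLC2A1 and SLC2A3 fell 3.60-fold (adjusted p = 1.47e-04) and 2.27-fold (adjusted p = 0.00131), and the phosphofructokinase PFKP rose 7.62-fold to 118 ± 34.7 CPM (adjusted p = 7.1e-06). G1/S genes were called lower (adjusted p = 0.0278, and adjusted p = 0.229 with an estimated correlation). The 1 called member of 18, the replication licensing factor CDT1, rose (1 higher and 1 lower adjusted over the list alone). Endothelium and blood fell in 2 of 3, also 2 adjusted over the list alone (adjusted p = 0.0407, adjusted p = 0.2 with an estimated correlation and adjusted p = 0.112 with the copy index). The VEGF receptor gene KDR fell 3.60-fold and the blood factor LMO2 6.96-fold.

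No call at Day3 was made for Notch with 2 higher and 0 lower of 12 (0.844), BMP-TGFβ targets 0 and 0 [0 and 3] of 13 (0.149), retinoic acid 2 and 0 of 11 (0.903) and immediate early 0 and 3 of 14 (0.364). The same held for G2/M 1 and 0 of 18 (0.844), circadian clock 0 and 3 of 12 (0.145), cholesterol synthesis 0 and 1 of 16 (0.0766, but called with the copy index, 0.0024), and stress 2 and 1 of 15 (0.568). Tissue lists without a call were definitive endoderm 0 and 1 [1 and 2] of 6 (0.619), neural 1 and 1 [1 and 2] of 11 (0.303), lateral and cardiac mesoderm 0 and 1 [1 and 1] of 7 (0.984), intermediate mesoderm 1 and 1 of 5 (0.844), sclerotome and myotome 1 and 1 of 4 (0.935), trophoblast 0 of 4 (0.903) and HOX 0 of 12 (0.0922). The median differed in sign from the mean and test for Notch, retinoic acid and immediate early genes, and the test from the median and mean for stress and intermediate mesoderm.

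From Day2 to Day3 1668 genes changed, with 1153 higher and 515 lower. The split was 2068 higher and 296 lower with log2(TPM + 1) in limma, and 1931 and 264 with log2(TPM + 0.1). With no minimum fold it was nearly even, at 1483 higher and 1407 lower. The total was 543 with the copy index (377 higher and 166 lower), 976 without Day3 replicate 3 (683 and 293) and 1008 with only the libraries of both days (699 and 309). The copy index ran from -1.08 to 1.31 among the Day3 libraries and from 1.68 to 2.08 at Day2. STMN2, DCX and MAP2, genes of neurons, stood at 286, 37.9 and 86.4 CPM at Day3 against 443, 87.9 and 205 CPM at Day2. The largest rises also held FOXD2 (41.9 ± 20.7 CPM, at least 143-fold), MAP1LC3C (28.4 CPM, at least 93.5-fold). They also held the pepsinogen genes PGA3 (76.4 ± 29.7 CPM, at least 236-fold) and PGA5 (70.8 ± 31.4 CPM, at least 214-fold; adjusted p = 0.0568 with DESeq2). These are nearly identical in sequence, so the share of each is uncertain. DLL1 rose to 204 ± 36.4 CPM (adjusted p = 0.0394), with an adjusted p of 0.0535 without Day1 replicate 3, 0.119 and 0.0962 without Day2 replicates 1 and 2, 0.092, 0.0506 and 0.0867 without Day3 replicates 1, 2 and 3, 0.136 with DESeq2, 0.23 with the index and 0.0727 with log2(TPM + 0.1). FOXC2, a somite factor, rose to 26.8 ± 4.43 CPM (adjusted p = 0.0111; 0.242 with DESeq2 and 0.0712 with the index). TBX6 fell to 0.507 CPM (adjusted p = 0.00263; 0.0637 with the index). EOMES fell to 1.89 CPM (adjusted p = 0.0183; 0.123 and 0.0778 without Day2 replicate 1 and Day3 replicate 3, 0.428 with the index, 0.116 and 0.145 with log2(TPM + 1) and log2(TPM + 0.1), 0.173 with only the libraries of both days). TDGF1 fell to 2.76 CPM (adjusted p = 0.00592; 0.0581 without Day2 replicate 1, 0.183 with the index, 0.119 with only the libraries of both days). TNFRSF11B, a decoy receptor gene, fell from 24.8 ± 36.8 CPM (ratio 159, interval 54.4 to 771; adjusted p = 0.00394; 0.062 without Day2 replicate 1, 0.152 with the index). LMO2 fell to 5.19 CPM (adjusted p = 0.00814; 0.0527 without Day2 replicate 1, 0.23 with the index). KDR had an adjusted p of 0.00176, and 0.0942 with the index. CDT1 went from 8.83 to 20.1 CPM (adjusted p = 0.0337; 0.0513 and 0.11 without Day2 replicates 1 and 2, 0.0546 and 0.15 without Day3 replicates 1 and 3, 0.44 with the index, 0.103 with only the libraries of both days). For calls lost with the index, the log2 change without and with it was 4.55 (SE 1.132) and 4.525 (1.386) for FOXC2, 1.774 (SE 0.588) and 1.583 (0.727) for DLL1 and -4.818 (SE 0.933) and -4.322 (1.279) for TBX6, with wider errors. It was -2.535 (SE 0.714) and -1.298 (0.852) for EOMES, -2.235 (SE 0.514) and -1.504 (0.632) for TDGF1 and -2.799 (SE 0.679) and -1.972 (0.906) for LMO2. It was -7.026 (SE 1.511) and -5.64 (2.213) for TNFRSF11B, -1.847 (SE 0.348) and -1.167 (0.393) for KDR and 1.192 (SE 0.381) and 0.685 (0.46) for CDT1. With DESeq2 it was 4.46 for FOXC2 and 1.734 for DLL1. The log2 change of SLC2A3 was -0.937 without Day2 replicate 3, and -0.871 and -0.874 with log2(TPM + 1) and log2(TPM + 0.1). LFNG and NANOG did not pass (adjusted p = 0.377 and 0.473), nor did DLL3 (0.0975) and SOX2 (0.251), which were called without Day0 replicate 3 (0.0246) and without Day3 replicate 2 (0.0106). DLL3 was also called with only the libraries of both days (0.0221).

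Across the 4 days 5562 of 12765 genes (43.6%) changed, 3496 with the copy index. Day-specific genes numbered 597, with 134 at Day0, 90 at Day1, 87 at Day2 and 286 at Day3. The clearest at Day0 were TRIML2, ZDHHC22, LRAT and IDO1, with fitted folds of 36.6, 27.0, 18.7 and 17.4 over the nearest other day. At Day1 they were DKK4, CER1, the growth factor FGF4 (71.0 CPM, 50.0-fold) and CALCR (46.5-fold). At Day2 they were MSGN1 (67.0-fold), SLC8A3 (10.7-fold), the matrix gene EGFLAM (106 ± 30.3 CPM, 10.2-fold) and RSPO3 (8.33-fold), and at Day3 PGA3, PGA5, RIPPLY1 and MEOX1. The Day2 genes also include the processed copy PABPC3, which is part of the copy index, and the neuronal genes DCX and MAP2. They are thus not presomitic markers alone. With the copy index the total was 318, with 62 at Day0, 16 at Day2 and 176 at Day3. Without Day1 replicate 2 there were 59 at Day1 and 40 at Day2, without Day2 replicate 3 there were 161 at Day2, and without Day3 replicate 3 there were 52 at Day2 and 186 at Day3. With TPM in limma Day0 had 204 with pseudocount 1, and Day2 had 57 and 38 with pseudocounts 1 and 0.1.

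The time course asked how presomitic mesoderm changed over 690 min. Over the course 11 of 18 presomitic genes fell and 3 rose, and 11 of 16 somite genes rose and 2 fell. Early values below are of the 30 and 60 min libraries and late values of the 660 and 690 min libraries, with n = 4 each. T fell from 117 ± 11.3 to 5.82 ± 2.1 CPM, MSGN1 from 42.4 ± 3.93 to 1.71 ± 0.44 CPM, and WNT5B 74.7-fold (trend log2 -7.37, SE 0.24, adjusted p = 3.95e-34). MEOX1 rose from 2.14 ± 0.986 to 329 ± 34.1 CPM (trend log2 7.54, SE 0.29, adjusted p = 1.8e-30) and TCF15 76.3-fold to 355 ± 30 CPM. RIPPLY1 rose from 0.706 to 302 ± 20.5 CPM (427-fold, trend adjusted p = 6.42e-30). PCDH8 (paraxial protocadherin), an adhesion gene of forming somites that is in the presomitic list, rose 125-fold from 14.8 ± 3.0 to 1850 ± 212 CPM (trend log2 7.55, SE 0.22, adjusted p = 5.63e-36). MESP2, which marks the next segment to form and is also in that list, had 2 counts early, 29.3 CPM late and a highest mean of 47.4 CPM at 540 min. Of 16 FGF-ERK targets 10 fell within the course, among them SPRY4 170-fold from 91.8 ± 38.2 CPM (trend adjusted p = 8.95e-16), DUSP6 74.4-fold from 289 ± 130 CPM and IL17RD 32.8-fold from 426 ± 44.8 CPM (trend adjusted p = 4.15e-31). The 3 that rose, named after their values were seen, were SPRY1 by 4.41-fold, DUSP5 by 2.45-fold and PHLDA1 by 1.4-fold (trend log2 1.327). PHLDA1 went from 45.3 ± 13.7 to 63.6 ± 19.9 CPM, with its lowest mean of 12.0 CPM at 150 min.

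**Figure D2:**
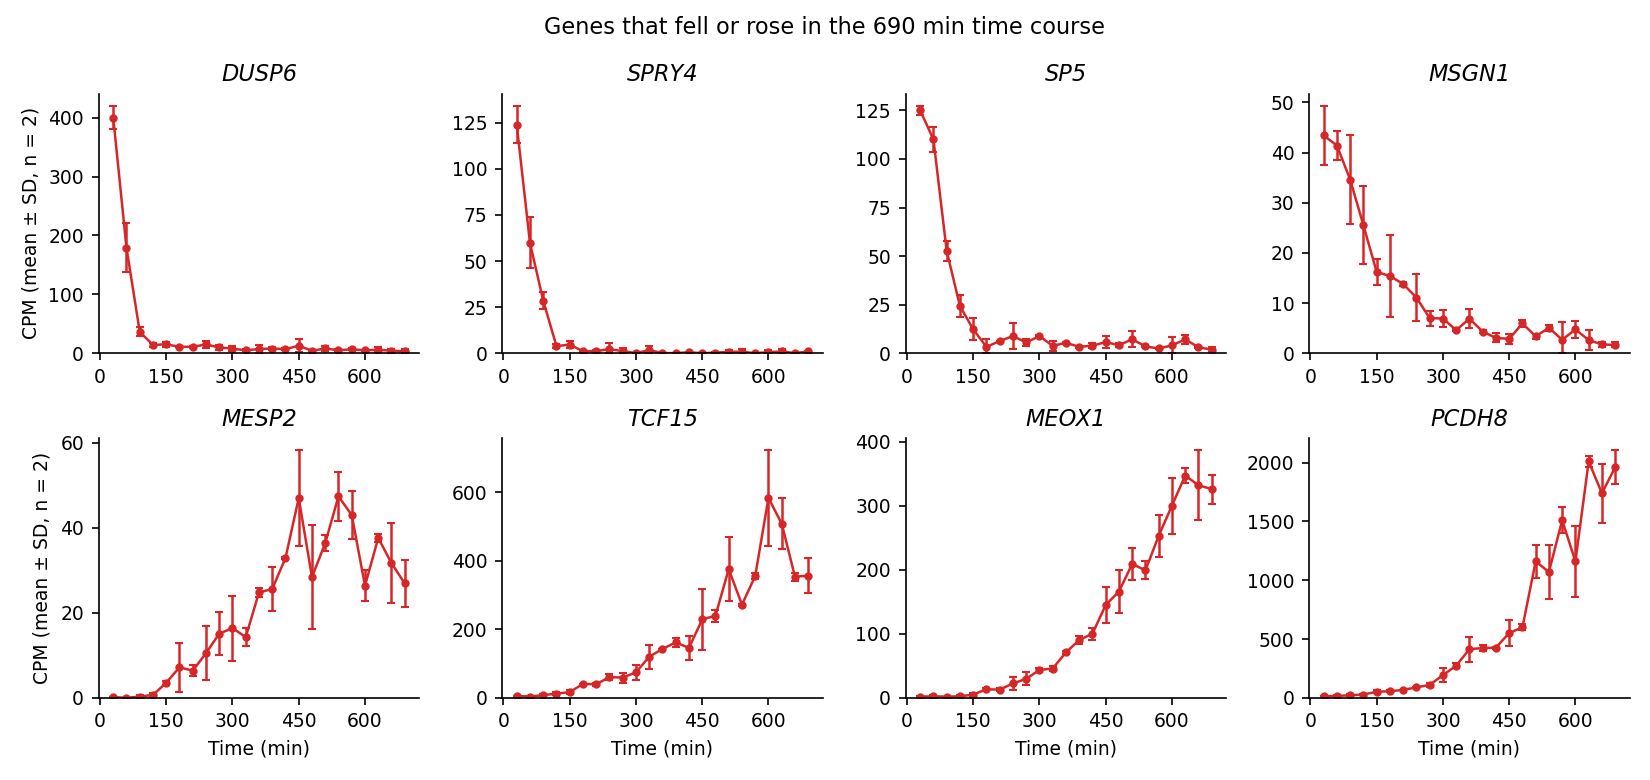
CPM against time for 8 genes of the course; lines join the means and bars are ± SD (n = 2). DUSP6, SPRY4, SP5 and MSGN1 were high early, and MESP2, TCF15, MEOX1 and PCDH8 were high late.

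Of 13653 genes 3940 (28.9%) differed among time points, 1472 with only 30 to 270 min and 795 with only 300 to 690 min. A total of 1655 had a trend of 1 log2 unit or more, 789 higher and 866 lower. With only 300 to 690 min the trend count was 1098 (545 lower). Lower trends numbered 554 with a step between 270 and 300 min, and higher trends 1191 with only 30 to 270 min. The genes that differed had their highest mean at 30 to 120 min in 830 cases, at 150 to 270 min in 1049, at 300 to 420 min in 367, at 450 to 570 min in 680 and at 600 to 690 min in 1014. By list, 11 of 16 somite genes rose and 2 fell (13 passed adjusted over the list alone; camera on the trend, adjusted p = 1.2e-12). In turn 11 of 18 presomitic genes fell and 3 rose (14 adjusted over the list alone; adjusted p = 1.87e-06). In the Notch pathway 6 of 16 rose and 1, HES7, fell (7 adjusted over the list alone; adjusted p = 3.94e-06). HEY1, a target, rose 38.0-fold to 225 ± 42.1 CPM, the ligand JAG1 6.31-fold to 286 ± 32.2 CPM and the feedback gene NRARP 8.21-fold to 111 ± 14.8 CPM. FGF-ERK targets fell in 10 and rose in 3 of 16 (14 adjusted over the list alone; adjusted p = 8.8e-06). Wnt targets fell in 8 and rose in 2 of 15 (10 adjusted over the list alone; adjusted p = 0.000547), with SP5 47.3-fold and NKD1 10.6-fold lower. Immediate early genes fell in 7 of 14 (7 adjusted over the list alone; adjusted p = 0.0066), with the transcription factor EGR1 31.4-fold lower. With an estimated correlation the camera adjusted p was 7.31e-09 for somite genes, 0.000353 for presomitic genes and 0.0496 for Wnt targets. It was 0.018 each for Notch genes, FGF-ERK targets and immediate early genes. HOX genes fell in 10 and rose in 2 of 20 (12 adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.234 with an estimated correlation). HOXB9 fell 96.0-fold from 20.8 CPM and HOXB1 from 40.5 CPM to 3 counts, while HOXD4 and HOXD3 rose 9.84-fold and 2.96-fold. CER1, highest at 600 min (70.7 CPM; trend adjusted p = 8.48e-25), PGA3 and PGA5 completed the 6 largest rises. The hair keratin KRT71, 67.7-fold lower, completed the falls.

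Among the other lists of the course, G1/S had 1 of 18 lower (1 adjusted over the list alone; adjusted p = 1.22e-08). Glycolysis had 1 of 18 lower (1 adjusted over the list alone; adjusted p = 0.00163), the transporter SLC2A1 by 6.46-fold. Stress genes had 6 of 16 lower and 1 higher (7 adjusted over the list alone; adjusted p = 0.00372) and intermediate mesoderm 2 of 6 higher (2 adjusted over the list alone; adjusted p = 0.0052). With an estimated correlation the camera adjusted p was 0.00144 for G1/S, 0.018 for glycolysis, 0.0198 for stress and 0.018 for intermediate mesoderm genes. Definitive endoderm was called higher with 2 of 7 higher and 3 lower (7 adjusted over the list alone; adjusted p = 0.0488, adjusted p = 0.0798 with an estimated correlation and adjusted p = 0.0556 with the copy index). Those that rose were CER1 and CXCR4. No call in the course was made for pluripotency with 1 higher and 4 lower of 15 (6 adjusted over the list alone; camera adjusted p = 0.297), mesendoderm 2 and 5 of 15 (7; 0.865), BMP-TGFβ targets 1 and 5 of 14 (6; 0.0642), or retinoic acid 1 and 2 of 11 (3; 0.742). Given likewise were G2/M 0 of 18 (0; 0.268), circadian clock 1 and 3 of 13 (4; 0.0685), and cholesterol synthesis 0 of 16 (0; 0.297). Tissue lists without a call were neural 2 and 2 of 12 (6; 0.297, but called higher with the copy index, 0.0336), lateral and cardiac mesoderm 2 and 3 of 8 (5; 0.865), endothelium and blood 0 and 2 of 6 (2; 0.297), sclerotome and myotome 2 and 1 of 7 (3; 0.0556, but called higher with the copy index, 0.0336) and trophoblast 1 and 1 of 5 (2; 0.75). The test was positive where the median was negative for retinoic acid, neural, lateral and cardiac mesoderm, and trophoblast. The copy index averaged -0.683 at 30 to 60 min, 0.692 at 90 to 270 min and -0.576 at 300 to 690 min. PAX6, a neural factor, moved with it at 5.29, 20 and 8.92 CPM, as did SOX2 at 22.6, 52.3 and 22.5 CPM.

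The course was next tested for a rhythm of 300 min, near the known period of the human segmentation clock. HES7 was high at the start, at 17.0 ± 4.74 CPM at 30 min, had a further high mean of 15.6 ± 6.68 CPM at 300 min and was lowest, at 1.68 CPM, at 570 min. It differed among time points (adjusted p = 4.06e-05) and declined 7.40-fold from 15.7 ± 3.7 to 2.12 ± 0.586 CPM (trend log2 -2.88, SE 0.36, adjusted p = 1.08e-09; 0.082 with only 30 to 270 min). A 300 min cycle around that trend was not called for HES7. Peak to trough was 1.59-fold (95% interval 1.09 to 2.33, unadjusted p = 0.054, adjusted p = 0.406). A fitted fold cannot lie under 1, so the lower limit of that interval is no test of a rhythm. Its adjusted p was 0.0456 at a period of 420 min and 0.0455 at 480 min. Its best period was 435 min (95% interval 306 to 480, the end of the search), with 410 min in replicate series 1 and 206 min in replicate series 2, and 221 min with a step between 270 and 300 min. LFNG, the clock gene that cycles with HES7 in embryos, passed the 300 min test (1.58-fold, log2 SE 0.15, adjusted p = 0.0334), with a fitted peak at 38.8 min, 465 ± 66.2 CPM at 300 min and 152 CPM at 120 min. Its best period was 380 min (344 to 454). APCDD1, a Wnt inhibitor, passed with 1.87-fold and a peak at 60.8 min (adjusted p = 0.0208; best period 387 min, 313 to 480). Both calls were lost with the copy index (adjusted p = 0.559 for both), at 1.49-fold for LFNG and 1.61-fold for APCDD1. With the step LFNG had a log2 of 0.77 (adjusted p = 0.101) and APCDD1 0.57 (0.777), against 0.66 and 0.90 without it. The calls were also lost with a linear trend (adjusted p = 0.416 for LFNG and 0.34 for APCDD1), without the first 3 time points (0.0811 and 0.0859) and with only 300 to 690 min (0.965 and 0.991). They were lost without replicate series 1 (0.61 for both) and 2 (0.286 and 0.391), and at periods of 150 to 270 min. With log2(TPM + 0.1) in limma the adjusted p was 0.0914 and 0.067, and with log2(TPM + 1) that of LFNG was 0.0802. Without APCDD1's most influential libraries its adjusted p was 0.0681, 0.0623 and 0.0603 (330 min replicate 2, 360 min replicate 1 and 390 min replicate 1). That of LFNG was 0.054 and 0.0608 without 150 min replicates 1 and 2, 0.0509 without 240 min replicate 1, 0.0761 and 0.0579 without 300 min replicates 1 and 2, and 0.0681 without 330 min replicate 2. It was 0.0623, 0.0665, 0.0578 and 0.0507 without replicate 1 of 360, 390, 510 and 540 min, and 0.0521 without 450 min replicate 2.

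**Figure D3:**
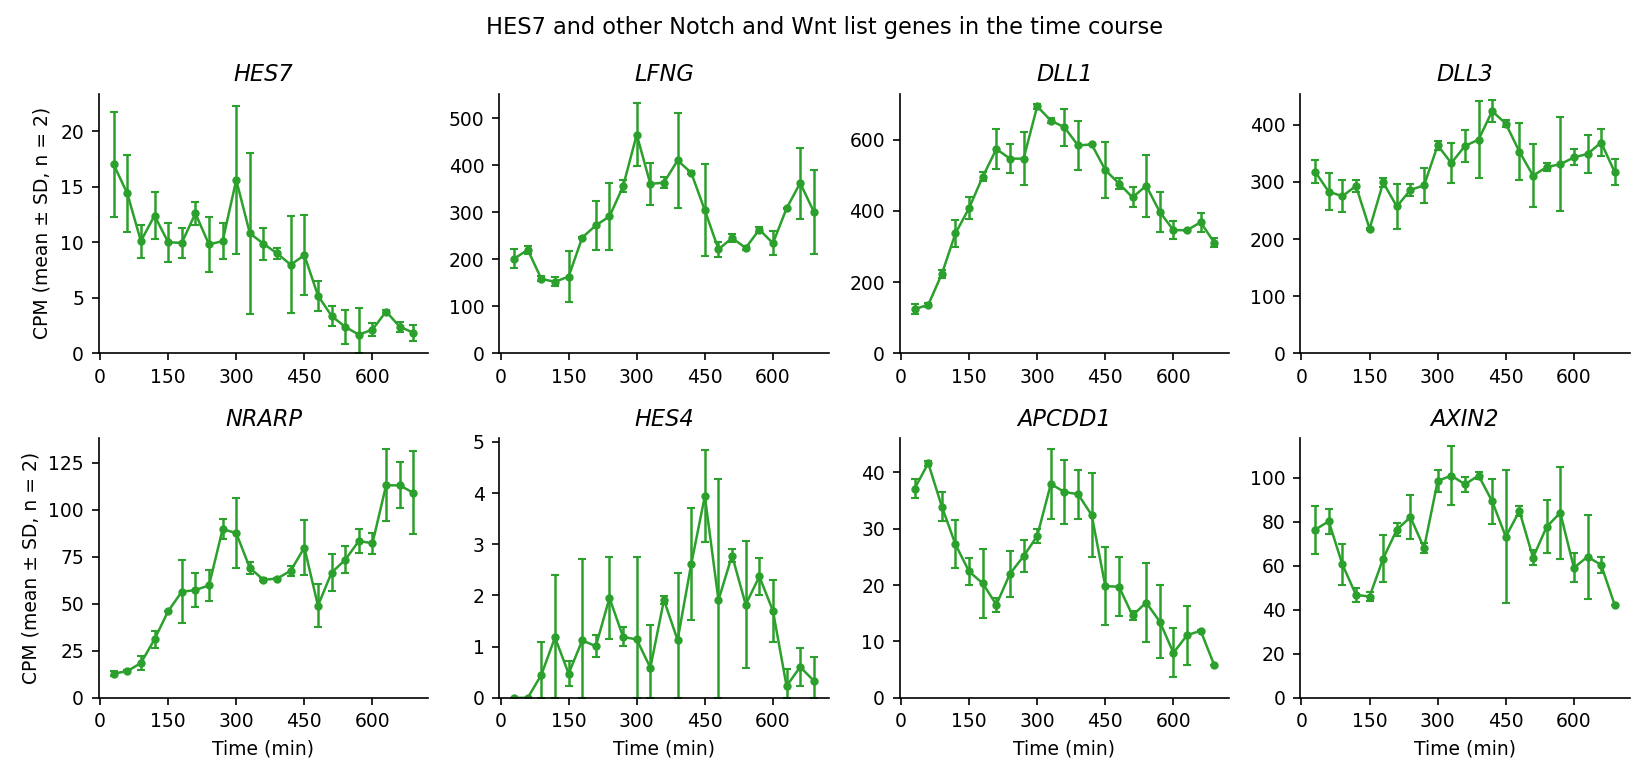
CPM against time for 8 genes of the segmentation clock and Wnt feedback; lines join the means and bars are ± SD (n = 2). HES7 had high means at 30 and 300 min, LFNG was highest at 300 min and lowest at 120 min, and DLL1 was highest at 300 min.

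In total 18 of 13653 genes passed the 300 min test, while 1725 had an unadjusted p under 0.05 in this model. Among called genes at 5 CPM or more, besides APCDD1, the largest fold was that of LDHAL6A, a lactate dehydrogenase (4.40-fold, peak at 194 min, adjusted p = 0.0458). PABPC3, a processed copy that is part of the copy index, followed (3.33-fold, 198 min, 0.0274). Next were the nuclear receptor NR2F2 (2.56-fold, 205 min, 0.0208), the peroxisome gene PEX7 (2.40-fold, 182 min, 0.0135) and the retinoid binder CRABP1 (2.39-fold, 210 min, 0.0352). Then came the BMP target ID2 (2.31-fold, 208 min, 0.0301), RPF2 (1.85-fold, 207 min, 0.047), GCA (1.79-fold, 261 min, 0.047) and the motor protein MYO5A (1.78-fold, 208 min, 0.0301). None of these kept the call with the copy index, which left GCA at 1.80-fold and the others at 1.23-fold to 1.75-fold. Leaving out each of the 46 libraries in turn ended the call of RPF2 with 26 of them, of GCA with 25, of LDHAL6A with 23 and of CRABP1 with 14. It ended that of MYO5A with 9, of PABPC3 and ID2 with 7 each, of NR2F2 with 2 and of PEX7 with 0. The other called genes were B4GALT5, FST, KLHDC2 and, at 0 counts in at least 32 of the 46 libraries, CDRT4, GRM5, HSPE1-MOB4 and SERF1A. The fitted folds of CDRT4, GRM5, HSPE1-MOB4 and SERF1A, 61.6 to 428, were the largest of all but rest on few libraries with counts. The count itself rests on single libraries. It was 1 without 330 min replicate 2, 3 without 360 min replicate 1, 6 without 390 min replicate 1, 7 without replicate 1 of 150 or 240 min, 10 without 300 min replicate 1, 390 min replicate 2 or 420 min replicate 1, and 11 without 510 min replicate 1. Higher counts were 29 without 180 min replicate 2, 33 without 450 min replicate 1, 56 without 120 min replicate 2, 57 without 570 min replicate 1, and 77 without 30 min replicate 2. The highest were 109 without 600 min replicate 2, 112 without 270 min replicate 2, 116 without 630 min replicate 1, 124 without 210 min replicate 1, 143 and 154 without 480 min replicates 1 and 2, 154 without 510 min replicate 2 and 155 without 540 min replicate 2. With each replicate series alone it was 1. The same test gave 2082 genes at a period of 480 min, and DESeq2 gave 195 at 300 min. With limma the real time order gave 8 genes, and of 100 orders, the real one included, 10 gave at least as many (highest 1037).

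Of the 18 genes 14 (77.8%, exact 95% interval 52.4 to 93.6) had fitted peaks within 60 min of each other in the first 11 and the last 12 time points. LFNG was not among them, with peaks at 282.6 and 76 min (93.4 min apart), while those of APCDD1 lay 20.9 min apart. HES7, not called, had peaks 114.3 min apart. The interval treats genes as independent, although 10 of the 18 had a rho above 0.5 with the copy index. No test is given, as the 18 genes were chosen by a fit over the whole course, which favours matching peaks. The share with matching peaks was 50% without replicate series 1. No gene list passed the test for rhythm genes (0 of 24 lists, Fisher's exact test, lowest adjusted p = 0.0939, 6 lists with an unadjusted p under 0.05). The presomitic, somite, Notch, Wnt, BMP-TGFβ and retinoic acid lists held 1 called gene each, against 18 of 13653 genes in all. Adjusted over the list alone, the rhythm was passed by 6 of 15 Wnt targets, 5 of 16 Notch genes and 4 of 12 neural genes. It was passed by 2 genes each of the presomitic, somite and cholesterol lists and by 1 each of the pluripotency, BMP-TGFβ, retinoic acid, immediate early, glycolysis and trophoblast lists. Of all genes tested 12.6% had an unadjusted p under 0.05 in this model. The counts adjusted over the list alone were not compared with other genes and are not given with the copy index. They do not show that these lists hold more rhythm genes than others. With a cubic trend 1 list was called, and with the replicate block 0.

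Set beside the daily series, the course began nearest to presomitic mesoderm and ended nearest to somite cells. The Pearson correlation with Day2, across 1000 genes that are not independent replicates, was 0.592 at 30 min, 0.654 at 60 min and 0.154 at 690 min, and with Day3 it went from 0.032 to 0.763. Day3 stood above Day2 from 300 min on (0.496 against 0.314), from 270 min without replicate series 2. The correlation with Day0 was -0.462 at 30 min and -0.573 at 690 min.

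**Figure D4:**
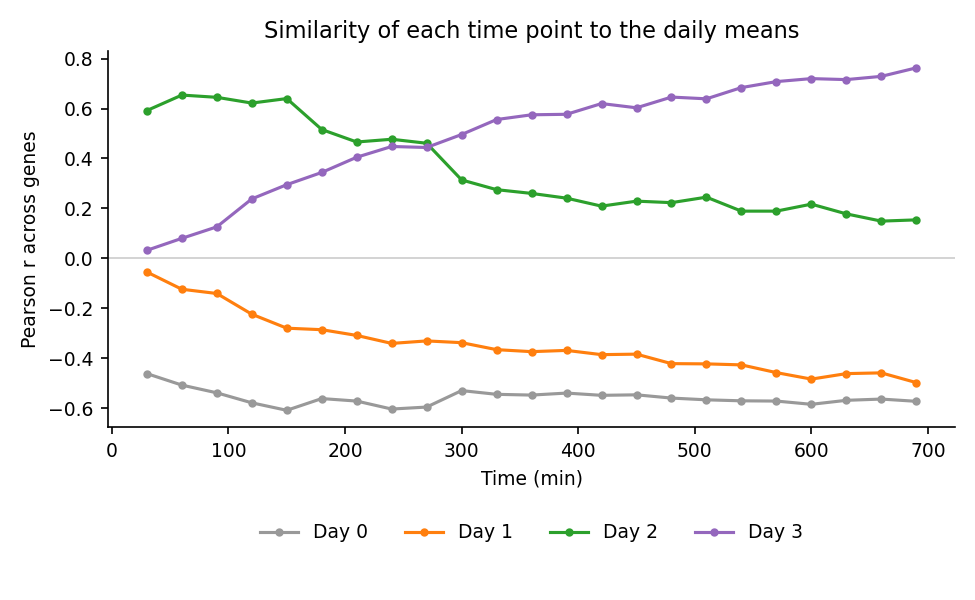
Pearson correlation across 1000 genes of each time point (mean of 2 libraries) with the mean of each day, against time. The line for Day3 crosses that for Day2 between 270 and 300 min.

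**Figure D5:**
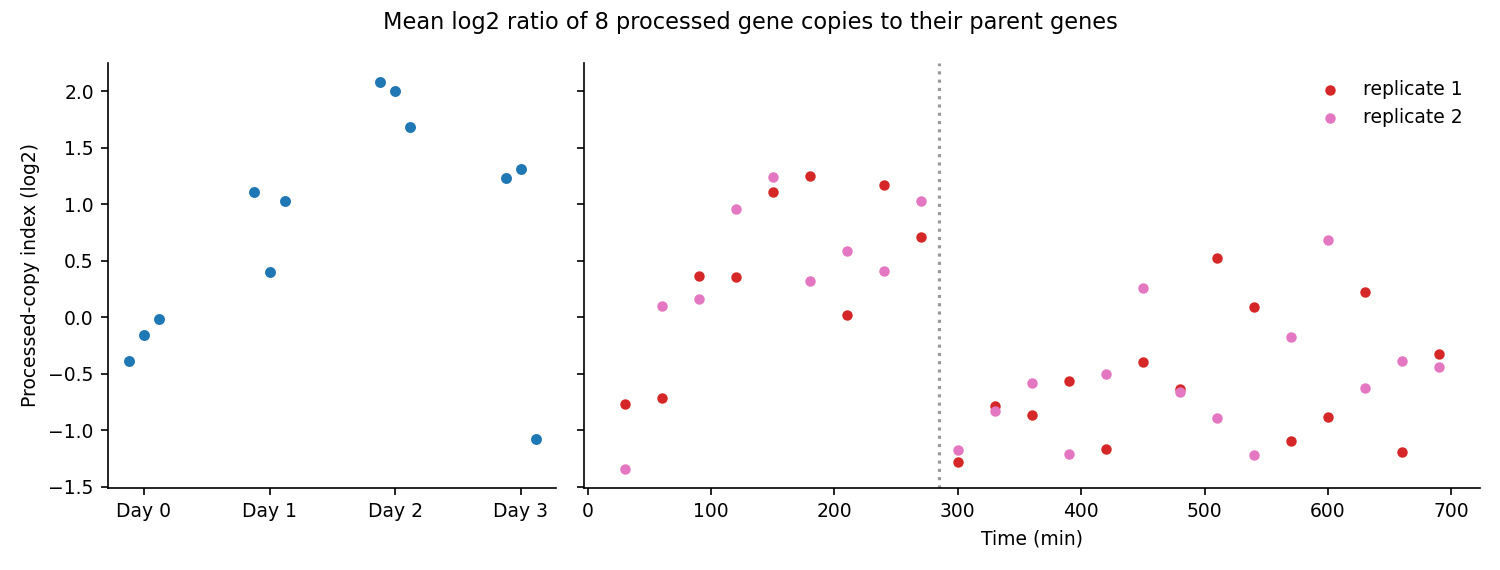
Mean log2 ratio of 8 processed gene copies to their parent genes, each pair centred on its mean over all libraries. Values are per library, for the days and against time in the course. The dotted line lies between 270 and 300 min. The index was highest at Day2 and, in the course, at 90 to 270 min.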

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

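Tests chosen only after the results were seen are the comparison of the days with the course, the copy index, the step and the separate windows of the course, and the tests of base errors or low depth, of a slow change and of HES7 oscillating in step.

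The change from Day2 to Day3 was set against the change from early (30 and 60 min) to late (660 and 690 min) in the course, in 1 edgeR fit of 14 libraries with a test of the difference itself, for 27 named genes. The 8 genes below differed, and the series stand apart in time span, culture and library set, so the source of the difference is open. T fell by 6.41 log2 between the days and by 4.32 in the course (difference -2.086, adjusted p = 0.0038). TBX6 fell by 4.87 and by 2.50 (difference -2.363, adjusted p = 0.00801), and MSGN1 by 6.84 and by 4.58 (difference -2.257, adjusted p = 0.0412). DLL3 was -1.26 between the days and 0.16 in the course (difference -1.425, adjusted p = 0.000144), and LFNG -0.36 and 0.62 (difference -0.986, adjusted p = 0.00671). MEOX1 rose by 10.31 and by 7.21 (difference 3.094, adjusted p = 0.00864), but with 1 count at Day2 its fitted value depends on the prior count. CER1, under 1 CPM on both days, was -0.34 between them and rose by 7.67 in the course (difference -8.01, adjusted p = 4.51e-06). PCDH8 was -0.07 between the days and rose by 6.95 in the course (difference -7.015, adjusted p = 3.61e-12).

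Processed gene copies and neural genes varied together across libraries. The neural mean took 8 of the 12 list genes other than SOX2 and OTX2, as the rest had low levels. Over the 46 course libraries it had r = 0.818 and rho = 0.821 with the copy index (permutation p = 1e-05 each, the smallest possible, adjusted 2.29e-05 and 4e-05 over 16 relations). Without the 2 farthest libraries r was 0.801. However, the most abundant of the 8, NES and ZIC2, ran the other way (rho -0.318 and -0.337). The permutations shuffled single libraries, but the index of the course moved in stretches of time. Its libraries are therefore not exchangeable, and the permutation p-values here may be too small. Neural cells in the cultures were taken to leave the ratio of other copies to their parents alone, which was not tested here. The median rho with the neural genes was 0.342 over 10 of 14 check pairs (above 0 in 7 pairs, below 0 in UTP14C, CSTF2T and EIF5AL1). Pairs left out for low copy levels (0 to 0.79 CPM) had -0.481, 0.063, -0.565 and -0.433. If the ratios do not depend on cell type, neural cells alone do not account for the whole pattern in the 10 pairs. That condition and the choice of pairs leave the question open. Base errors or low depth cannot be told apart from other sources: neural genes followed the index within 300 to 690 min (rho = 0.685, permutation p = 5e-05; r = 0.739, p = 2e-05, 0.689 without 2 libraries), but there too total counts ran against it (rho = -0.582, permutation p = 0.00149; r = -0.482, p = 0.00915, -0.278 without 2). The daily libraries gave r = 0.795 and rho = 0.762 (permutation p = 0.00234 and 0.00542), with total counts against the index (r = -0.942, rho = -0.93, permutation p = 1e-05 and 5e-05; r -0.917 without 2). The constant added to the counts raises the index at low depth where copies are scarce, so part of this relation may be built in. Reads of another organism or of other libraries may be the source, which stays a hypothesis. Both the neural genes and the median of the 10 check pairs followed the index over the course (lower rho 0.424). The pairs left out had a rho of -0.509, 0.149, -0.72 and -0.505 with it. These relations restate the pattern to be explained, and the index and check pairs are both ratios of copies to parents. Other sources could give them too, so they do not favour such reads. Mouse sequence was not used here, and the submitters' processing notes list mm8 beside hg19 without saying why. The relation of neural genes to the check pairs was also weak within 300 to 690 min (r = 0.265, rho = 0.226, permutation p = 0.171 and 0.245).

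The 18 genes that pass the 300 min test include few of the clock, and of 100 time orders tested with limma, the real one included, 10 gave at least the 8 genes of the real order (highest 1037), so chance is not excluded. With the copy index as a covariate 2 of the 18 still passed, HSPE1-MOB4 and SERF1A, both at 0 counts in 40 of the 46 libraries, and 10 of the 18 had a rho above 0.5 with the index (CRABP1 0.857 and NR2F2 0.840, besides PABPC3, which is part of the index and so no evidence). The fitted fold fell from 2.56 to 1.44 for NR2F2 and from 2.39 to 1.36 for CRABP1, for which the copy signal may be the source, but it was 1.79 and 1.80 for GCA and 1.58 and 1.49 for LFNG, so the lost calls of these (adjusted p = 0.149 and 0.559) do not speak for it. A slow change that is not periodic may account for others, as the period interval held 300 min in only 7 of the 18. A rhythm of longer period would also leave out 300 min (LFNG 344 to 454 min), so this count cannot tell these apart. Of the 7, CDRT4, GRM5 and SERF1A had intervals of 180 to 480 min, the whole range searched. Oscillation of HES7 in step across the culture cannot be told apart from the copy signal or a slow change. HES7 had an unadjusted p of 0.054 and an adjusted p of 0.406. Its interval of 1.09 to 2.33-fold is no test of a rhythm, as a fitted fold cannot lie under 1. In simulations at its depth, tested by least squares, a 1.5-fold cycle reached an unadjusted p under 0.05 in 55% and a 2-fold cycle in 93.5%.

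Other splits of the daily libraries were run for 6 results. For any change the real days gave 5562 genes and the highest of the other splits 339, and for day-specific genes 597 against 107. In each case 1 of 100 splits, the real one, gave as many, which excludes only a random sorting of these libraries into days. Wrong splits mix the days and widen the spread, so fewer calls were likely from the start. Chance differences between single cultures or library batches are not excluded, as replicates may be technical. For called lists it was 30 against 28, and although 1 of 100 splits, the real one, gave as many, a wrong grouping gave nearly as many, so the number of called lists says little about them. For the transitions, with 661, 1499 and 1668 genes, the highest other splits gave 0, 0 and 2 genes, but the 10 splits of 6 libraries are too few for a share under 0.05.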

How the results depend on the processing

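Settings chosen only after the data were seen are the copy index, the step between 270 and 300 min, the separate windows of the course, the list test on the trend and keeping the genes tested with all libraries when a library was left out. For the 14 main results 293 of 361 recomputed values stayed within 1.5-fold of the count or on the same side of the threshold, 38 were weaker, 26 stronger, 4 moved and 0 reversed. For the other results, which are named genes and counts by direction or day, 4101 of 4549 stayed, 426 were weaker, 22 stronger and 0 reversed. Apart from fits that leave out a library or a replicate series, 1332 of 1549 of these stayed. The verdict stayed for 169 of 169 with DESeq2 size factors, 164 of 167 with the DESeq2 test, 166 of 169 with the replicate block and 129 of 169 with the copy index. Deviations of libraries that share a replicate number were not alike (median r 0.019 over 18 daily pairs and 0.001 over 506 course pairs), so the numbers do not pair, and with the block the transitions had 666, 1488 and 1638 genes. The block also brought calls for the BMP-TGFβ targets (adjusted p = 0.0264) and G2/M (0.0486) at Day1 and ended that of definitive endoderm at Day2 (0.094). With it the rhythm count was 14, and RPF2, GCA and LDHAL6A lost their calls (adjusted p = 0.0523 each). The cause of the changes below was not tested, except where fewer libraries, time points or a fold limit make them by construction. Depth limits HES7, at 42 counts in 4 late libraries, and genes under the floor.

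With the copy index the daily test gave 3496 genes, Day2 against Day1 698, Day3 against Day2 543, day-specific genes 318 and the rhythm test 3. Index ranges did not overlap between successive days, so the lower daily counts need not be due to the copies. With a minimum of 2 log2 units the transitions gave 297, 571 and 708 and day-specific genes 236; with no minimum Day2 against Day1 gave 2569 and Day3 against Day2 2890 (1483 higher and 1407 lower); with only the 2 days compared Day1 against Day0 gave 1139 and Day3 against Day2 1008. Of the daily lists 13 were called with an estimated correlation and 63 by fry in either direction. In the course any change gave 1472 genes with only 30 to 270 min and 795 with only 300 to 690 min, where the trend gave 1098 and the rhythm 3.

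The rhythm test was the least stable. It gave 644 genes with no filter, 2 and 1 on log2(TPM + 1) and log2(TPM + 0.1), 7 without the first 3 time points, 3 with the step, 30 with a linear and 235 with a cubic trend and 195 with DESeq2. At periods of 150, 180, 210, 240 and 270 min it gave 2, 0, 1, 3 and 2 genes, and at 330, 360, 420 and 480 min 615, 1153, 1875 and 2082. Of 100 time orders tested with limma, the real one included, 10 gave at least the 8 genes of the real order. The period of HES7 was 221 min with the step, peaks lay within 30 min of each other in 50% of genes, and 1 list was called for rhythm with a cubic trend.

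Leaving out libraries or a replicate series gave 4673 to 5966 genes for any change over the days, 437 to 826, 875 to 1826 and 976 to 2059 for the transitions, 444 to 705 day-specific genes, 3527 to 4507 for any change in the course, 1284 to 1695 for the trend and 1 to 155 for the rhythm. The period of HES7 ran from 206 to 480 min, the share of genes with matching peaks from 50 to 77.8%, and the time when Day3 stood above Day2 from 270 to 300 min.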

Other observations

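The comparison of the days with the course and the count of changes between successive time points were chosen only after the results were seen. The somite step of the days and the time course shared much of their gene response. Of 12587 genes tested in libraries that the comparisons do not share, 2044 were called from Day2 to Day3 and 928 from early to late in the course, and 475 in both. Of these 278 rose in both and 182 fell in both, against 60.9 and 18.5 from the margins, and 15 went opposite ways (r = 0.888 across the 475 genes, which are not independent). Further genes that rose over the course include the cartilage and sclerotome factors SOX9 (3.69-fold, to 125 CPM) and TWIST1 (6.61-fold, to 37.3 CPM), the retinol dehydrogenase RDH10 (13.4-fold, to 186 CPM) and APLNR (3.64-fold, to 2421 CPM).

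Genes of the Notch pathway and of segment formation reached their highest means at different times. Of the Notch list HEY1, HEY2, NRARP and JAG1 were highest at 660 min and the receptors NOTCH1 and NOTCH2 at 690 min. DLL1 was highest at 300 min (694 CPM, from 130 CPM early), as was the target HEYL (200 CPM), DLL3 was highest at 420 min (424 CPM), and MESP2 at 540 min (47.4 CPM). RIPPLY2, a repressor made at the segment border, was highest at 570 min (141 CPM) and TCF15 at 600 min (584 CPM). The spread of these times was not tested.

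The step from 270 to 300 min stood apart. Of 6697 genes at 20 CPM or more 135 changed at least 2-fold there, against at most 72 between any other neighbouring time points. The copy index went from 0.867 to -1.23 at the same step, the correlation with Day3 passed that with Day2 there, and DLL1, LFNG and HEYL were highest at 300 min. The labels do not say how the time points were collected.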
